A study of Mus musculus with 35 samples.

How the data were processed

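The samples are 35 libraries of RNA from whole mouse lung, made per the labels by Trizol extraction of a homogenate aliquot and a Watchmaker Genomics mRNA kit. They fall into 12 groups by agent (naphthalene or none), day label (2, 5 or 7) and genotype, with 3 libraries per group except KO mice at day 7 after naphthalene, which have 2. The control genotype (C) is RORaf/f, mice whose Rora gene carries loxP sites. The KO genotype is RORaf/fIl7riCre, in which a Cre recombinase expressed from the Il7r locus acts on those sites in cells that express, or whose ancestors expressed, Il7r. The series design gives the age as 14 days and states no separate age for each day label, so the age of the untreated mice of days 2, 5 and 7 is left open. Each library was read as a separate mouse, and p-values rest on the spread between mice.

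The deposited table holds counts per gene, 1 line per Ensembl mouse gene with its symbol, for 57186 genes. All values are whole numbers of 0 or more and the column totals differ between libraries, which is what unnormalised counts show. The labels name the genome build GRCm39 and DESeq2 without giving the role of either. The aligner, the counting program and the annotation release are not given in the sources used here. The reference copy at hand is of another mouse build, so no positions are given, and genes are identified by symbol and Ensembl identifier only. Symbols occur on more than 1 gene for 232 symbols, and 535 genes have none.

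Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr on the 12 groups, which left 20606 genes to test out of 39417 with any read. The kept genes hold at least 99.87% of the counts of every library. Libraries were scaled by TMM factors, and the CPM given in the text (counts scaled to a library total of 1 M, M being mega) were computed from the deposited counts with these factors. A single fit of the 12 group means used robust quasi-likelihood dispersion (common biological coefficient of variation 0.222, 23 residual degrees of freedom, median prior degrees of freedom 8.24). Each comparison is a contrast of group means tested with edgeR's two-sided quasi-likelihood F-test, with Benjamini-Hochberg adjustment over all genes of the comparison and a threshold of 0.05 on the adjusted p. Log2 changes are given with the standard error of the contrast (SE), and CPM with the SD between the mice of a group.

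The 18 comparisons are the naphthalene effect in each genotype at each day (treated minus untreated with the same genotype and day label), the genotype effect at each combination of treatment and day (KO minus control), the genotype difference in the naphthalene effect at each day, the genotype effect averaged over the 6 combinations, and the day 7 minus day 2 difference in the naphthalene effect and in untreated mice. Their tests, 43 gene lists with 608 members in all, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Gene lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 43 lists of a comparison. The same lists were tested with camera under an estimated correlation between genes and with fry, whose p asks whether the genes of a list move, on balance, one way and does not compare the list with other genes. For list members, counts of called genes are given over all genes tested and adjusted over the list alone.

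Named genes follow a rule. In each comparison these are the 5 largest increases and the 5 largest decreases among called genes with a mean of at least 5 CPM in 1 of the compared groups, no overlap between the libraries of the compared groups (10% of genes separate so by chance for 3 against 3), and a symbol that is not a gene model, a pseudogene or a segment of an immunoglobulin or T cell receptor. The condition on overlap was not applied to comparisons of more than 2 groups. For each list described, the member with the smallest p in each direction and the 2 members with the highest mean CPM are named. Comparisons with at most 10 called genes name them as well, and genotype comparisons also give Rora, Il7r and members of the ILC2 and eosinophil lists. Some genes that the rule picks are left out of the text. Genes outside the rule are said to be chosen after their values were seen.

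Totals ran from 10.7 to 21.06 M counts per library, with a median of 16.16 M, so that 1 read equals 0.049 to 0.089 CPM. For a called gene with at most 3 reads over a compared group, the ratio of pooled CPM is given with its exact Clopper-Pearson 95% interval, which covers counting error only. The tests were checked on simulated data drawn from the fitted means and dispersions with 200 changed genes. At day 2 in control mice edgeR recovered 50.5% of 2-fold and 76.8% of 4-fold changes, with 6 false calls among 131. On the same simulated data DESeq2 recovered 53.6% and 78.8%, with 14 false calls among 144. For the averaged genotype effect edgeR recovered 91.9% of 2-fold changes, which were set alike in all 6 combinations of treatment and day. For the genotype difference at day 2 it recovered 16.2% of 2-fold and 47.4% of 4-fold changes. A ciliated cell list raised 1.5-fold was called by all of the list tests with 0 other lists called. The simulated genes were drawn independently, so this does not show how the list tests behave where the genes of a list correlate.

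The alternatives were DESeq2's Wald test with its own size factors, RLE in place of TMM factors, no filter on low counts, the replicate number as a block in a fit of the compared groups, a fit of only the compared groups, the mean of Y-linked genes as a covariate for sex, the letter in the library name as a batch term, and leaving out each library in turn. The letters are not explained by the labels. Letter a marks the treated libraries of day 2 and letters b and i those of day 5, letters k and n mark the untreated libraries of day 2 and f and o those of day 5, and every library of day 7 carries letter p. A letter term could therefore be fitted only for genotype comparisons of days 2 and 5, for the genotype differences of those days and for the averaged genotype effect. By X- and Y-linked transcripts 17 libraries came from females and 18 from males, with 0 mixed, and every group held both sexes. No library was left out of the tests. Replicate numbers were not used as pairs, because in 0 of the comparisons with 3 pairs did the deviations from the group means correlate above 0.1 in every pair.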

Results

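The data are gene counts from whole lungs of mice with the control genotype (RORaf/f) and of KO mice (RORaf/fIl7riCre), untreated or at 2, 5 or 7 days after naphthalene. The design asks what naphthalene does to the lung over these days and whether the loss of RORa in cells with Il7r expression changes it. The label of the control genotype names no Cre, so genotype comparisons cannot separate the loss of RORa from the Cre at Il7r. RORa is a nuclear receptor needed for group 2 innate lymphoid cells (ILC2s), the cell type named in the title of the series. Each of 11 groups had 3 mice, and KO mice at day 7 after naphthalene had 2. Library totals had group means from 13.6 ± 0.78 M counts (SD, n = 2) in KO mice at day 7 after naphthalene to 18.6 ± 1.2 M (n = 3) in untreated control mice of day 2. The 45S pre-ribosomal transcript Rn18s-rs5 took 0.715% to 8.12% of a library, with the highest share in replicate 1 of the untreated KO mice of day 7. Haemoglobin transcripts took 0.175% to 2.14%.

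At day 2 after naphthalene, a compound that injures club cells of the airway through their own cytochrome P450 enzymes, control lungs had far less of the main club cell transcript and far more of several epithelial transcripts that untreated lungs hardly expressed. Scgb1a1 (ENSMUSG00000024653), the secretoglobin of club cells, fell from 6850 ± 718 CPM (SD, n = 3) to 563 ± 182 CPM, a log2 change of -3.60 ± 0.29 (SE, adjusted p = 1.21e-09). Prss22, a serine protease of airway epithelium, rose from 0.142 ± 0.157 to 29.7 ± 9.53 CPM, a log2 change of 7.64 ± 0.82 (adjusted p = 3.36e-07). The next largest increases were Psapl1 at 7.15 ± 0.56, the EGF receptor ligand Ereg at 5.28 ± 0.51, the acute-phase protein Orm1 at 4.97 ± 0.61 and Syt8 at 4.18 ± 0.44 on the log2 scale. Other large decreases were the trefoil peptide Tff2 at -3.81 ± 0.90, the red cell anion exchanger Slc4a1 at -3.63 ± 0.51 and the cadherin Cdh22 at -2.77 ± 0.45. In all, 774 of 20606 genes were called by edgeR, 530 higher and 244 lower, and 598 of them changed at least 2-fold.

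KO lungs at day 2 showed a like picture. Scgb1a1 fell from 6560 ± 1830 to 426 ± 36.1 CPM (n = 3), a log2 change of -3.95 ± 0.29 (adjusted p = 3.35e-10). Prss22 reached 18.7 ± 4.25 CPM from 3 reads over the 3 untreated libraries, a pooled ratio of 270 with a 95% interval from 92.2 to 1310. Psapl1 rose by 6.71 ± 0.58, Ereg by 4.85 ± 0.50, the neutrophil surface glycoprotein Cd177 by 4.84 ± 0.44 and the mucosal chemokine Cxcl17 by 4.06 ± 0.44 on the log2 scale. Other large decreases were Tff2 at -4.66 ± 0.97, Lypd2 at -2.98 ± 0.47 and the secretoglobin Scgb3a1 at -2.73 ± 0.66. In all, 565 genes were called, 411 higher and 154 lower.

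The airway lists moved apart at day 2. Of 18 club cell genes, 6 fell and 12 were not called in control mice (7 lower and 2 higher when adjusted over the list alone), with a median log2 change of -0.495 (list test adjusted p = 1.05e-06, adjusted p = 0.0736 with an estimated correlation). Besides Scgb1a1, the member with the second highest level was the carbonyl reductase Cbr2, at -0.35 ± 0.24 and not called. Selenbp1 had the smallest p among members with a higher value, at 0.70 ± 0.22 and not called. In KO mice 7 club cell genes fell and 11 were not called (9 lower and 1 higher adjusted over the list alone, median -0.607, adjusted p = 0.0484 with an estimated correlation). Of 20 ciliated cell genes, which encode parts of motile cilia and their regulators, 14 rose in control mice and 11 in KO mice, and 16 in each genotype when adjusted over the list alone. Cfap126 had the smallest p in control mice, at 1.54 ± 0.18 (adjusted p = 2.04e-06), and Cimap3 in KO mice, at 2.11 ± 0.26 (adjusted p = 4.77e-06). The cilia regulator Foxj1 rose from 42.0 ± 9.27 to 134 ± 15.6 CPM in control mice and from 26.6 ± 7.51 to 89.5 ± 10.8 CPM in KO mice. Tppp3, the member with the highest level, was not called (0.02 ± 0.21 and -0.36 ± 0.21). The list medians were 1.14 and 1.02, with adjusted p = 0.00213 and 0.0051 with an estimated correlation.

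Injury and basal cell genes rose as well. Of 15 injury-associated epithelial genes, 11 rose in control mice and 9 in KO mice (12 and 11 adjusted over the list alone, where 1 and 2 others were lower), with medians of 1.36 and 1.16. The EGF receptor ligand Areg, also a product of ILC2s, went from 2.69 ± 0.735 to 42.8 ± 1.05 CPM in control mice (log2 change 3.99 ± 0.41, adjusted p = 1.04e-07) and from 2.62 ± 1.41 to 39.1 ± 6.28 CPM in KO mice (3.94 ± 0.41, adjusted p = 2.86e-07). The stress-induced chaperone Clu rose by 1.48 ± 0.25 and 1.63 ± 0.25. Krt7 was not called (0.52 ± 0.18 and 0.43 ± 0.18), and Ly6d was the lower member with the smallest p (-0.85 ± 0.35 and -0.91 ± 0.35, not called). The injury list had adjusted p = 0.00735 in control mice and 0.0457 in KO mice with an estimated correlation. Among 9 basal cell genes, markers of airway stem cells, 4 rose in control mice and 2 in KO mice (6 and 4 adjusted over the list alone, medians 1.79 and 1.2, adjusted p = 0.0125 and 0.0457 with an estimated correlation). Krt17 went from 2 reads to 53 over the control groups, a pooled ratio of 28.6 (95% interval 7.54 to 243), and from 2 to 42 in KO mice, a ratio of 18.6 (4.83 to 158). Sfn rose by 0.96 ± 0.23 in control mice, and Krt15 was not called there (2.13 ± 0.78) or in KO mice (1.69 ± 0.79). NRF2 targets, enzymes of the response to oxidants and electrophiles, counted 6 higher, 1 lower and 12 not called of 19 in control mice and 5 higher of 19 in KO mice (9 and 5 higher and 1 and 1 lower adjusted over the list alone). Akr1b8 rose by 2.04 ± 0.23 and 1.42 ± 0.23, Gclc by 1.03 ± 0.19 and 0.77 ± 0.19. Gsta2 fell by 2.03 in control mice (SE 0.54), and Gstm1 was not called (0.71 ± 0.22 and 0.53 ± 0.22). That list had adjusted p = 0.0193 in control mice and adjusted p = 0.212 in KO mice with an estimated correlation.

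Immune and blood genes changed too at day 2. Of 25 interferon-stimulated genes, 12 fell in control mice and 6 in KO mice (20 and 10 adjusted over the list alone), and 24 and 25 had values below 0. Rtp4 went from 41.9 ± 0.582 to 18.3 ± 2.09 CPM in control mice (-1.19 ± 0.18, adjusted p = 8.3e-05) and fell by 1.22 in KO mice (SE 0.18). Ifit2 was the 1 member above 0 in control mice (0.06 ± 0.25). Bst2 and Rigi, the members with the highest levels, were at -0.71 ± 0.23 and -0.48 ± 0.22 in control mice and not called. The list median was -0.945 in control mice (adjusted p = 0.0107 with an estimated correlation) and -0.714 in KO mice (adjusted p = 0.0632 with an estimated correlation). Of 13 natural killer (NK) cell genes, 2 fell in control mice (11 adjusted over the list alone, median -1.61, adjusted p = 0.0438 with an estimated correlation) and 1 in KO mice (3 adjusted over the list alone, median -0.933, adjusted p = 0.212 with an estimated correlation), with the granzyme Gzma at -1.65 ± 0.45 and -1.57 ± 0.44. Ccl5 and Nkg7, its most abundant members, were not called in control mice (-0.73 ± 0.44 and -0.83 ± 0.32). Of 10 red blood cell genes, 4 fell in control mice and 1 in KO mice (9 and 2 adjusted over the list alone, medians -1.50 and -1.05, adjusted p = 0.0193 and 0.212 with an estimated correlation). Haemoglobin took 0.2% ± 0.032 of counts in treated control mice against 0.438% ± 0.047 in untreated ones (n = 3). Mitochondrial transcripts took 1.65% ± 0.015 against 1.04% ± 0.25 in control mice and 2.04% ± 0.48 against 1.4% ± 0.14 in KO mice (n = 3), and whether this reflects RNA quality was not tested. Acute inflammation genes counted 3 higher of 18 in control mice and 2 in KO mice (7 and 5 adjusted over the list alone, medians 0.58 and 0.50), with adjusted p = 0.00213 and 0.0051 with an estimated correlation. Its most abundant members Icam1 and Lcn2 were not called in control mice (0.27 ± 0.38 and 0.86 ± 0.43). The 14 neutrophil genes were all above 0 in both genotypes. Of these, 4 were higher in control mice, led by lactoferrin (Ltf, 1.91 ± 0.42), and 3 in KO mice, led by the decoy receptor Il1r2 (3.22 ± 0.66). With 4 and 7 called when adjusted over the list alone, that list had adjusted p = 0.151 and 0.217 with an estimated correlation.

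Of the 43 lists, camera called 18 in control mice and 20 in KO mice at day 2 with the preset correlation. Of these, 8 and 5 held with an estimated correlation. Leaving out replicate 1 of the untreated control mice gave 479 called genes, and leaving out replicate 1 or 2 of the treated control mice gave 468 or 515. In KO mice the count was 1099, 239 or 276 without untreated replicate 1, 2 or 3, and 319 or 216 without treated replicate 1 or 3. A replicate block gave 167 in control mice and 629 in KO mice, and a fit of only the compared groups 606 and 261. Treated and untreated libraries of days 2 and 5 carry different letters in their names, so at those days treatment and letter cannot be told apart.

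**Figure D1:**
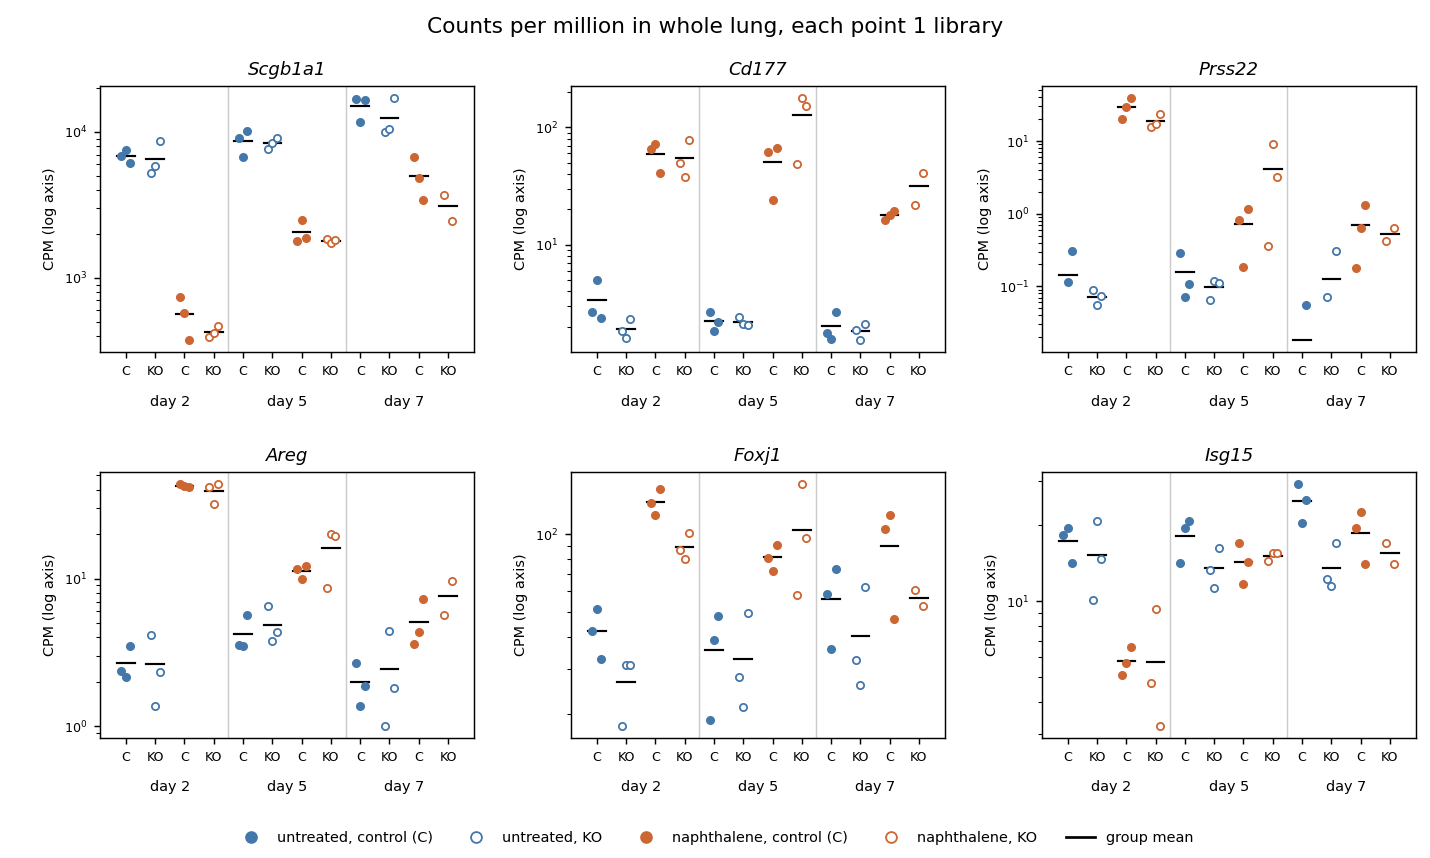
CPM (log axis) of 6 genes in every library, by day, genotype and treatment, with black lines at the group means; libraries with no Prss22 read are not drawn. Scgb1a1 lies lower in every treated than in every untreated library of its day, from 426 ± 36.1 CPM in treated KO mice of day 2 to 4970 ± 1680 CPM in treated control mice of day 7, while Cd177 lies higher throughout.

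At day 5 in control mice the club cell transcript was still lower and Cd177 was the largest increase. Scgb1a1 was at 2060 ± 372 CPM against 8700 ± 1770 CPM in untreated mice (n = 3), a log2 change of -2.08 ± 0.27 (adjusted p = 0.000123). Cd177 (ENSMUSG00000052212) rose from 2.23 ± 0.434 to 51.1 ± 23.5 CPM, a log2 change of 4.51 ± 0.43 (adjusted p = 2.62e-07). Further increases were Cxcl17 at 3.04 ± 0.43, the transcription factor Zbtb16 at 2.80 ± 0.55, the uroplakin Upk3a at 2.63 ± 0.48 and myoglobin (Mb) at 2.59 ± 0.66. Decreases included the macrophage gene Aif1 at -2.15 ± 0.49, Tbc1d10c at -1.98 ± 0.35 and Snhg20 at -1.87 ± 0.51. Mb was at 1.87 ± 1.80 CPM in the untreated control mice of day 5 and at 8.53 to 17.2 CPM in the other untreated groups, so its increase goes with a low untreated mean. Of 9 cardiac muscle genes 2 rose (3 adjusted over the list alone, median 0.311, adjusted p = 0.441 with an estimated correlation), Nppa at 3.38 ± 0.84 and Myl7 at 1.37 ± 0.34, while the abundant Actc1 and Tnnt2 were at 0.19 ± 0.23 and 0.11 ± 0.30, not called. Myl7 too was lowest in that group, at 22.2 ± 11.9 CPM. Whether these libraries held less heart tissue was not tested. In all, 492 genes were called, 227 higher and 265 lower.

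These control-mouse calls of day 5 rest on few libraries. Replicate 1 of the untreated control mice of day 5 held a set of transcripts far above all others, among them P2ry12 at 159 CPM against at most 3.92 CPM in the other 34 libraries (chosen after its values were seen). Without it 23 genes were called, 19 higher and 4 lower, all of them among the 492. Aif1 was then at -0.53 (adjusted p = 0.495). Calls also ended for Zbtb16 at 2.55 (adjusted p = 0.113), Upk3a at 2.41 (0.0622), Mb at 2.52 (0.194), Tbc1d10c at -1.49 (0.0643) and Snhg20 at -1.71 (0.208), with folds closer to those of all libraries and 1 library fewer. Scgb1a1 stayed at -2.04 (adjusted p = 0.000983) and Cd177 at 4.66 (adjusted p = 1.36e-05). Leaving out untreated replicate 2 or 3 gave 154 or 3544 calls, and leaving out treated replicate 1, 2 or 3 gave 81, 61 or 95. DESeq2 called 1329 genes, a fit of only the compared groups 26, a replicate block 9 and a fit without a filter on low counts 2118.

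**Figure D2:**
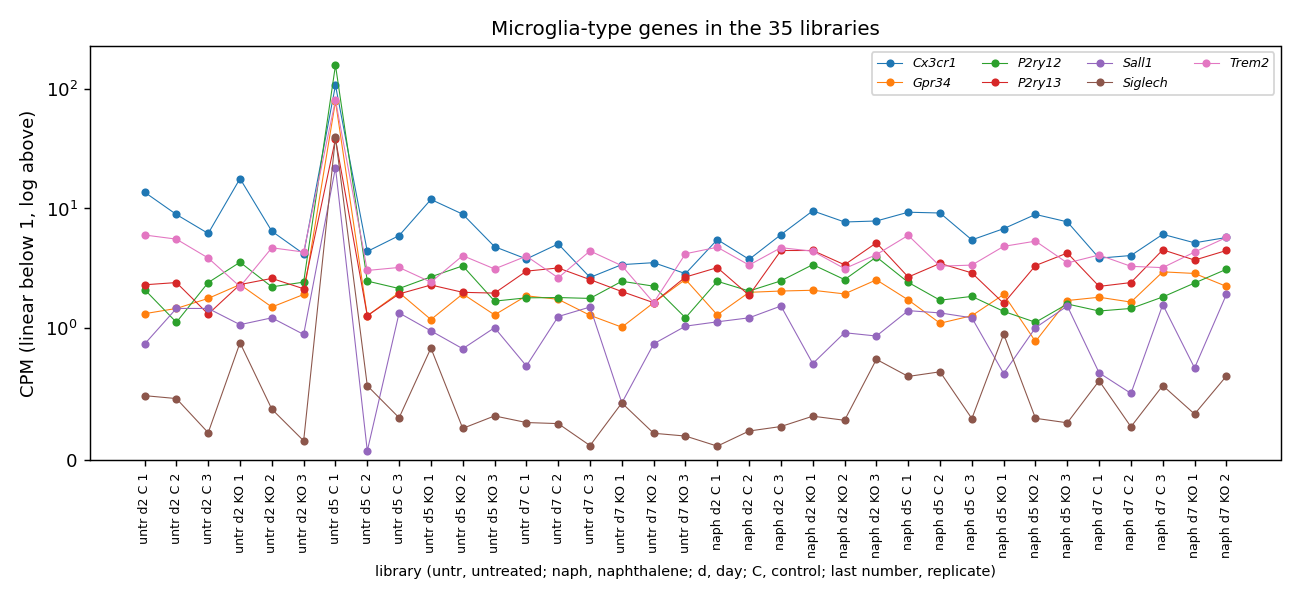
CPM of 7 genes, chosen after their values were seen, in all 35 libraries (log axis, linear below 1). Points are libraries, and lines join the points of a gene. In replicate 1 of the untreated control mice of day 5 P2ry12 is at 159 CPM against at most 3.92 CPM elsewhere, Siglech at 39.5 against 0.951 CPM and Cx3cr1 at 108 against 17.8 CPM.

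In KO mice at day 5, Cd177 rose from 2.19 ± 0.190 to 126 ± 68.4 CPM (n = 3), a log2 change of 5.85 ± 0.45 (adjusted p = 1.07e-09). Scgb1a1 fell from 8400 ± 712 to 1800 ± 65 CPM, a log2 change of -2.23 ± 0.27 (adjusted p = 7.97e-06). The next increases were Cxcl17 at 3.38 ± 0.43, the secretory-cell disulfide isomerase Agr2 at 3.35 ± 0.56, the keratin Krt15 at 3.27 ± 0.77 and the amine oxidase Aoc1 at 3.20 ± 0.37. Further decreases included Apol11b at -2.17 ± 0.50 and Zfp711 at -1.58 ± 0.32. In all, 272 genes were called, 235 higher and 37 lower. Without untreated replicate 1, 2 or 3 the count was 124, 95 or 175, and without treated replicate 1, 2 or 3 it was 901, 68 or 129. DESeq2 called 449 genes, a fit of only the compared groups 24, a replicate block 69 and a fit without a filter on low counts 635.

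Ciliated cell genes were still higher at day 5, with 5 of 20 called in control mice and 9 in KO mice (12 and 15 adjusted over the list alone, medians 0.60 and 0.75). Fam183b led in control mice at 1.19 ± 0.22 and Cfap126 in KO mice at 1.22 ± 0.18, and Foxj1 was not called in control mice (1.2 ± 0.37) and rose by 1.66 ± 0.38 in KO mice. The list had adjusted p = 0.349 in control mice and 0.00955 in KO mice with an estimated correlation. The neutrophil list did not move with Cd177 at day 5. In control mice 8 of 14 genes were above 0 and 0 were called (2 higher and 1 lower adjusted over the list alone, median 0.059, adjusted p = 0.83 with an estimated correlation), with Lcn2 at 1.52 ± 0.44 and S100a9 at 0.02 ± 0.55. In KO mice Lcn2 rose by 1.78 ± 0.44 and was the 1 called gene (2 adjusted over the list alone, median 0.392, adjusted p = 0.679 with an estimated correlation). All 15 B cell genes were below 0 in both genotypes. Of these, 7 were called in control mice and 0 in KO mice (11 and 7 adjusted over the list alone, medians -1.02 and -0.769), and adjusted p = 0.349 and 0.172 with an estimated correlation. Cd79b, part of the B cell receptor, was at -1.28 ± 0.25 in control mice (adjusted p = 0.00752), and Ighm and Cd79a, the members with the highest levels, were at -0.76 ± 0.23 (not called) and -1.31 ± 0.28 (called). In KO mice Ms4a1 had the smallest p (-1.23 ± 0.36, not called). Of 14 alveolar type 2 genes, all above 0 in both genotypes, 2 rose in control mice and 1 in KO mice (10 and 2 adjusted over the list alone, medians 0.88 and 0.62, adjusted p = 0.349 and 0.609 with an estimated correlation). The fatty acid desaturase Scd1 led, with 2090 ± 85.9 CPM against 373 ± 125 CPM in control mice (2.49 ± 0.41, adjusted p = 0.00157) and 1.96 ± 0.40 in KO mice. The surfactant genes Sftpc and Sftpb were not called in control mice (1.01 ± 0.34 and 0.78 ± 0.41). Fibroblast genes in control mice counted 2 higher of 15 (7 adjusted over the list alone, median 0.64, adjusted p = 0.349 with an estimated correlation), with the matrix proteoglycan Lum at 1.63 ± 0.26 and the abundant members Mfap4 and Col3a1 not called (0.87 ± 0.35 and 1.00 ± 0.33). Without untreated replicate 1, the counts in control mice were 0 for the B cell list (median -0.713) and 1 each for the ciliated cell, alveolar type 2 and fibroblast lists (medians 0.581, 0.681 and 0.575). Their adjusted p was then 0.288, 0.288, 0.326 and 0.288 with an estimated correlation. The neutrophil list then had 0 called and a median of 0.319 (adjusted p = 0.867 with an estimated correlation). The B cell calls of control mice were thus lost without that library. These list counts were not refitted without other libraries, so the loss is not shown to be particular to it.

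Type 2 response genes, which include products of goblet cells and of macrophages under IL-4 and IL-13, counted 1 higher of 17 in control mice and 4 in KO mice at day 5 (3 and 7 adjusted over the list alone, medians 0.50 and 1.02), with adjusted p = 0.349 and 0.0137 with an estimated correlation. Agr2 had the smallest p in both (3.29 ± 0.57 and 3.35 ± 0.56). The macrophage chitinase-like gene Chil3 rose in KO mice from 117 ± 38.3 to 418 ± 219 CPM (1.84 ± 0.35, adjusted p = 0.00332). Retnla was not called in KO mice (3.31 ± 0.86, adjusted p = 0.0508) or in control mice (0.06 ± 0.78). Acute inflammation genes in KO mice counted 3 higher of 18, adjusted over the list alone as well, with Orm1 at 2.51 ± 0.60, Lcn2 at 1.78 ± 0.44 and Icam1 at 0.72 ± 0.39, which was not called (adjusted p = 0.00882 with an estimated correlation). In control mice camera called 13 lists with the preset correlation, and 0 held with an estimated correlation. In KO mice it called 14, and 3 held. Fry, which does not compare a list with other genes, called 14 lists in control mice and 8 in KO mice.

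At day 7, where all libraries share 1 letter, few genes passed the test in either genotype. The 8 called genes in control mice included Cd177 at 3.13 ± 0.42, the protease inhibitor Wfdc3 at 2.42 ± 0.30, Aoc1 at 1.71 ± 0.34, AU040972 at 1.70 ± 0.28, the hormone gene Ghrl at 1.66 ± 0.32 and Gm867 at 1.14 ± 0.18, all higher, and 2 lower genes. The lower ones included Scgb1a1 at -1.59 ± 0.27 (over all 8, adjusted p from 0.000109 to 0.0463, n = 3). Scgb1a1 was at 4970 ± 1680 against 15000 ± 2900 CPM, and Cd177 at 17.9 ± 1.58 against 2.02 ± 0.594 CPM. In KO mice 13 genes rose and 2 fell. By the rule these included Cd177 (31.4 ± 13.5 CPM, n = 2, against 1.85 ± 0.283, n = 3; 4.07 ± 0.45), Wfdc3 at 2.46 ± 0.33, Ghrl at 2.11 ± 0.34, AU040972 at 2.08 ± 0.30 and the mucin Muc4 at 1.34 ± 0.25. The lower genes included Scgb1a1 at -2.01 ± 0.32. DESeq2 called 15 genes in control mice and 31 in KO mice. In control mice the count was 3, 3 or 5 without untreated replicate 1, 2 or 3 and 5, 4 or 3 without treated replicate 1, 2 or 3, and a fit of only the compared groups called 3. In KO mice it was 8 without untreated replicate 1, 8 without untreated replicate 3 and 4 without treated replicate 2, a fit in which the single treated library left is assumed to vary as the other groups do. With the replicate number as a replicate block edgeR called 0 genes in control mice (332 at an unadjusted p under 0.05) and 46 in KO mice. Without a filter on low counts it called 45 and 161.

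Lists still moved at day 7 with few single genes called. All 20 ciliated cell genes in control mice and 19 in KO mice were above 0, with 0 called over all genes and 7 in each genotype adjusted over the list alone (medians 0.53 and 0.57, adjusted p = 0.0414 and 0.049 with an estimated correlation). Dnah9 had the smallest p in control mice (0.89 ± 0.20) and Rsph1 in KO mice (0.80 ± 0.21). Type 2 response genes were above 0 for 14 of 17 members in control mice and 17 of 17 in KO mice, with 0 and 2 called (2 and 8 adjusted over the list alone, medians 0.745 and 0.73, adjusted p = 0.0414 and 0.00282 with an estimated correlation). The called members were Agr2 (3.99 ± 0.66, adjusted p = 0.00295) and the chemokine Ccl8 (4.88 ± 0.93, adjusted p = 0.0172). The 2 treated KO libraries differed widely for both, with Agr2 at 1.74 and 6.98 CPM and Ccl8 at 0.626 and 5.08 CPM. Retnla was at 331 ± 163 CPM against 124 ± 88.1 CPM in control mice and at 281 ± 60.5 against 42.1 ± 24 CPM in KO mice, and was called in neither (1.42 ± 0.79 and 2.74 ± 0.88). Acute inflammation genes were above 0 for 15 of 18 members in each genotype, with 0 called (0 and 4 adjusted over the list alone, medians 0.47 and 0.757, adjusted p = 0.0414 and 0.00105 with an estimated correlation). All 14 neutrophil genes in KO mice were above 0, with 0 called and 12 higher when adjusted over the list alone (median 1.72, adjusted p = 0.306 with an estimated correlation). Ltf had the smallest p (2.04 ± 0.47, adjusted p = 0.0948), and S100a9 and Lcn2, the members with the highest levels, were at 1.79 ± 0.61 and 1.19 ± 0.47. These libraries also differed for neutrophil genes, with S100a9 at 214 and 29.7 CPM, Mmp9 at 48.9 and 7.38 CPM and the inflammation gene Il1b at 28.7 and 3.41 CPM. The 15 B cell genes in KO mice were all below 0, with 0 called and 10 lower when adjusted over the list alone (median -0.949, adjusted p = 0.065 with an estimated correlation). In all, camera called 10 lists in control mice and 17 in KO mice with the preset correlation. In each genotype 3 held with an estimated correlation. By fry the 3 lists of control mice had adjusted p = 0.0664 (ciliated), 0.0664 (acute inflammation) and 0.0791 (type 2 response).

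**Figure D3:**
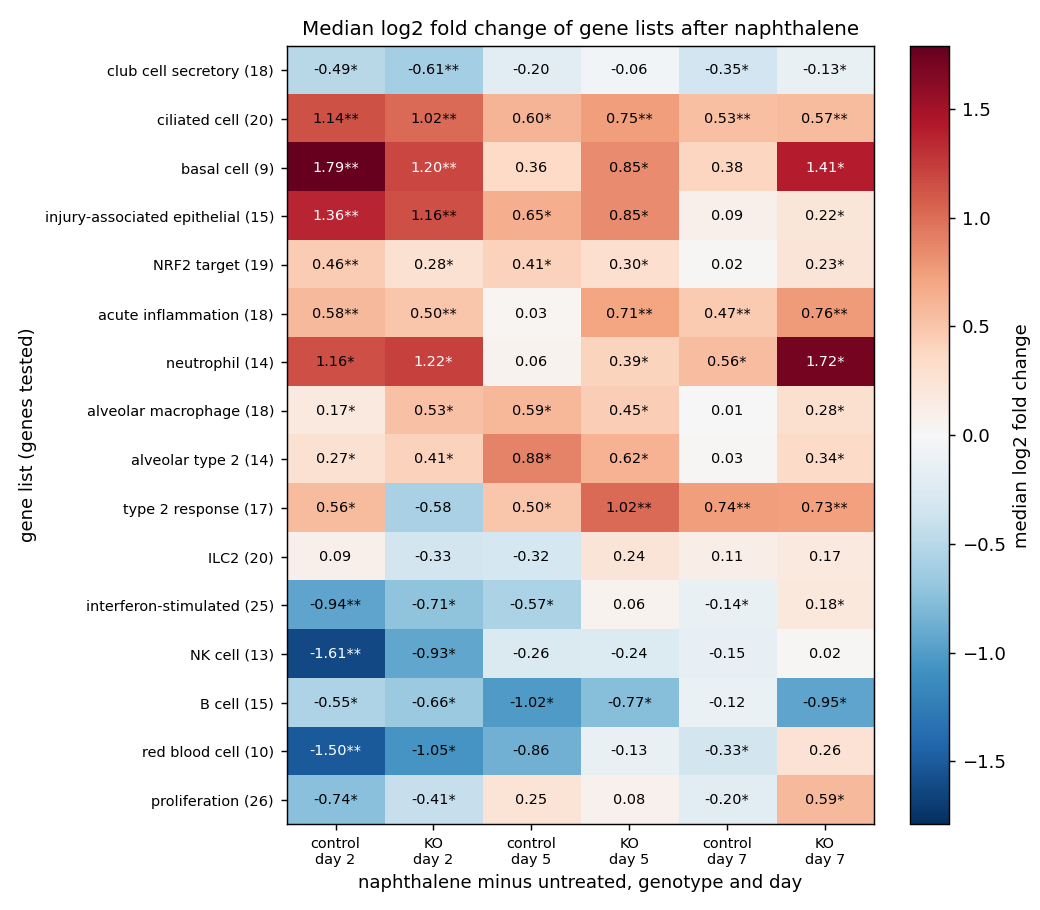
Median log2 change after naphthalene of 16 gene lists (genes tested in brackets) in 6 combinations of genotype and day. A star marks adjusted p under 0.05 by camera with the preset correlation and a double star also with an estimated correlation. The ciliated list is above 0 in every column, from 0.53 to 1.14, and carries the double star in all columns but that of control mice at day 5 (0.60).

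The genotypes share much of the naphthalene response at day 2, and less can be said of the later days. At day 2, 315 genes rose in both genotypes where 10.6 would be expected from independent lists, and 83 fell in both where 1.82 would be expected, with 0 genes called in opposite directions. Of the 774 genes called in control mice, 99.4% had the same sign in KO mice, and the log2 changes of all genes correlated at 0.645 between the genotypes. At day 5, 83 genes rose and 10 fell in both (2.59 and 0.476 expected), and without replicate 1 of the untreated control mice 14 rose and 4 fell in both. Of the 492 genes called in control mice 86.2% had the same sign in KO mice, with a slope of 0.426, and the correlation over all genes was 0.363. At day 7, 4 genes rose and 2 fell in both, and that correlation was 0.0676. The groups behind these overlaps share no libraries. At days 2 and 5 the genotypes share library letters, so a difference between letters could also give shared genes.

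The test of the genotype difference in the naphthalene effect called 0 genes at day 2, day 5 and day 7 by edgeR, with 371, 1869 and 882 genes at an unadjusted p under 0.05. DESeq2 called 0 at each day. At this replication the self-test recovered 47.4% of 4-fold differences at day 2, so a smaller difference between the genotypes was mostly not detectable. Camera with the preset correlation called 13 lists at day 2, 1 at day 5 and 6 at day 7, and 0 of them held with an estimated correlation. Without replicate 1 of the untreated control mice it called 6 lists at day 5, again 0 of them with an estimated correlation (lowest adjusted p = 0.0851, acute inflammation). For the type 2 response list the effect of naphthalene was lower in KO than in control mice at day 2 (median -0.435, adjusted p = 0.443 with an estimated correlation) and higher at day 7 (median 0.766, adjusted p = 0.607 with an estimated correlation). At day 7 this went with lower values in untreated KO mice (median -0.74 against untreated control mice). Chil3 and Retnla, its most abundant members, differed by -0.01 ± 0.48 and -1.88 ± 1.13 at day 2 and by 0.77 ± 0.50 and 1.31 ± 1.16 at day 7, none of them called. All 15 B cell genes had a negative difference at day 7 (median -0.781, adjusted p = 0.607 with an estimated correlation), with Cd79a at -1.01 ± 0.41 and Ighm at -0.90 ± 0.35, not called.

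In whole lung the targeted gene was not called in any genotype comparison. Rora (ENSMUSG00000032238) was at 36.3 ± 6.03, 45.6 ± 3.63 and 47.7 ± 4.57 CPM in untreated control mice of days 2, 5 and 7 and at 46.7 ± 14.5, 47.8 ± 6.66 and 51.7 ± 8.65 CPM in untreated KO mice (n = 3). After naphthalene it was at 47.6 ± 8.28, 39.4 ± 1.79 and 43.6 ± 8.03 CPM in control mice (n = 3) and at 57.6 ± 10.7, 35.1 ± 8.70 (n = 3) and 50.6 ± 8.92 CPM (n = 2) in KO mice. The averaged log2 difference was 0.14 ± 0.09 (adjusted p = 0.398). Whole-lung counts per gene mix all cell types and do not separate the deleted part of Rora, so they check nothing about the deletion in ILC2s.

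Il7r (ENSMUSG00000003882), the locus that carries the Cre and encodes the receptor for IL-7, had values of 4.97 ± 4.92, 10.6 ± 1.69 and 8.59 ± 0.511 CPM in untreated control mice of days 2, 5 and 7 and 6.17 ± 2.05, 4.91 ± 0.188 and 4.19 ± 0.900 CPM in untreated KO mice (n = 3). After naphthalene the values were 8.44 ± 0.444, 3.78 ± 1.12 and 7.67 ± 1.91 CPM in control mice and 4.82 ± 1.23, 6.37 ± 4.24 and 5.68 ± 0.629 CPM in KO mice. The log2 differences ran from -1.10 ± 0.42 in untreated mice of day 5 to 0.75 ± 0.43 in treated mice of day 5, with an average of -0.39 ± 0.18 (adjusted p = 0.315), none of them called.

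ILC2 genes did not pass the test in any genotype comparison. The IL-33 receptor gene Il1rl1 was at 4.70 ± 0.560 CPM in untreated control mice of day 5 against 2.48 ± 0.363 in KO mice (-0.92 ± 0.39, adjusted p = 0.486) and at 3.77 ± 0.756 against 1.86 ± 0.616 CPM at day 7 (-1.01 ± 0.41, adjusted p = 0.952). The IL-25 receptor gene Il17rb differed by -1.17 ± 0.53 in untreated mice of day 7 and by -1.49 ± 0.63 in treated mice of day 7. Its mean was higher in KO mice among untreated mice of day 2 (1.31 ± 0.308 against 0.872 ± 0.727 CPM). The same held among treated mice of day 5 (1.42 ± 0.988 against 0.692 ± 0.286 CPM), and it was lower in KO mice in the other combinations. Gata3, a transcription factor of ILC2s and T cells, had an averaged difference of 0.03 ± 0.12, and Areg of 0.23 ± 0.16. Il5 lay at 0.102 to 0.393 CPM in the group means, a few reads per library, so its levels were not resolved at this depth. The 20 ILC2 genes as a list were called lower by the preset correlation in untreated mice of day 7 (median -0.417, 14 of 20 below 0, adjusted p = 0.151 with an estimated correlation). They were also called lower in treated mice of day 7 (median -0.428, adjusted p = 0.553 with an estimated correlation) and higher in treated mice of day 5 (median 0.384, adjusted p = 0.763 with an estimated correlation). Its 2 most abundant members Hs3st1 and Dgat2 had averaged differences of -0.00 ± 0.09 and -0.20 ± 0.12. Of the 10 eosinophil genes 0 were called in any genotype comparison over all genes or adjusted over the list alone, with Siglecf at an averaged 0.07 ± 0.11 and Ear1 at -0.22 ± 0.11. In untreated mice of day 7 the eosinophil list had a median of 0.09 and a mean of 0.01 while its test pointed down (adjusted p = 0.733). In untreated mice of day 2 the ILC2 list had a median of -0.07 and a mean of 0.04 and the eosinophil list a median of -0.191 and a mean of 0.0642, with both tests pointing up (adjusted p = 0.854 and 0.945).

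By edgeR 0 genes were called for genotype in untreated mice of days 2, 5 and 7, with 934, 1969 and 691 genes at an unadjusted p under 0.05, and 0 in treated mice of those days, with 1207, 521 and 1448. The effect averaged over the 6 combinations also called 0, with 3084 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.154. DESeq2 called 25 genes in untreated mice of day 5, 1 in treated mice of day 5 and 0 in the other genotype comparisons. In untreated mice of day 5, edgeR called 39 and 197 genes without control replicate 2 and 3, and in treated mice of day 5 it called 3 without KO replicate 1. With the replicate number as a replicate block it called 2 genes in untreated mice of day 5, 123 in untreated mice of day 7 and 1437 in treated mice of day 7. In treated mice of day 7 that block was fitted to 3 control and 2 KO libraries, which leave little to estimate the spread from. Deviations from the group means correlated at 0.2 and -0.16 for its 2 pairs of equal replicate numbers. In untreated mice of day 7 they correlated at 0.07, 0.36 and 0.4. A fit of only the compared groups called 2 in untreated mice of day 5 and 86 in treated mice of day 2. Without a filter on low counts edgeR called 21, 245 and 33 genes in untreated mice of days 2, 5 and 7. It then called 70, 20 and 231 in treated mice of those days and 503 for the averaged effect. On simulated data for the averaged effect 59 of 173 calls were false without the filter. With the filter the self-test for that effect recovered 91.9% of 2-fold changes, which were set alike in all 6 combinations. It does not show how well a genotype effect that varies with day or treatment would be recovered.

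Camera with the preset correlation called 15 lists in untreated mice of day 7, all lower in KO mice, and 0 of them held with an estimated correlation. Type 2 response genes had a median of -0.74 there (14 of 17 below 0, 2 lower adjusted over the list alone, adjusted p = 0.0649 with an estimated correlation), with Clca1 at 0.256 ± 0.344 against 9.25 ± 9.35 CPM and Retnla at 42.1 ± 24 against 124 ± 88.1 CPM, neither called. Interferon-stimulated genes had a median of -0.492 (23 of 25 below 0, 3 lower adjusted over the list alone, adjusted p = 0.22 with an estimated correlation), with Bst2 at -0.49 ± 0.23. At day 7 after naphthalene, 14 of 15 B cell genes were below 0 in KO mice (median -0.81, 8 lower adjusted over the list alone, adjusted p = 0.553 with an estimated correlation), with Cd79a at -1.09 ± 0.32. Over the 6 combinations, the club cell and B cell lists were called lower (medians -0.169 and -0.213, adjusted p = 0.84 with an estimated correlation for each), with Scgb3a1 at -0.79 ± 0.26 and Spib at -0.41 ± 0.13, not called. Without replicate 1 of the untreated control mice of day 5 the B cell list was no longer called (median -0.136, adjusted p = 0.0562), while the alarmin, glucocorticoid target and immediate early lists were (adjusted p = 0.0392, 0.0047 and 0.0452). With an estimated correlation their adjusted p was 0.656, 0.656 and 0.806.

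**Figure D4:**
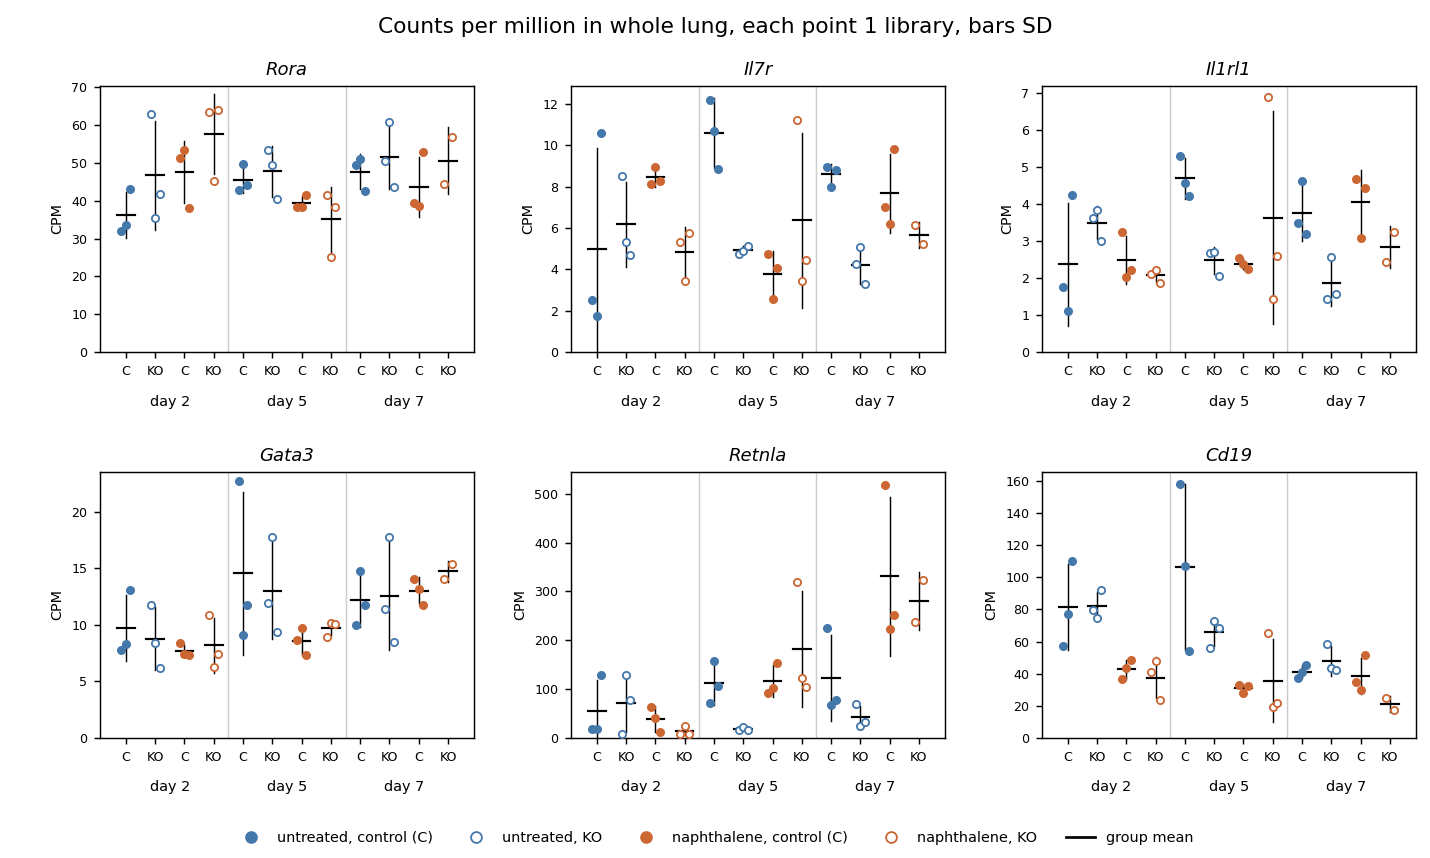
CPM of 6 genes in every library, by day, genotype and treatment, with black lines at the group means and bars of 1 SD. Rora overlaps between genotypes in all 6 combinations of treatment and day, with group means from 35.1 to 57.6 CPM, and Il7r has group means from 3.78 to 10.6 CPM.

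The naphthalene response differed between day 7 and day 2. Averaged over genotypes, 209 genes were called, 95 with a higher and 114 with a lower effect at day 7. The club cell secretoglobin Scgb3a2 had fallen by 1.89 in control mice at day 2 (SE 0.36) and stood above the untreated level at day 7 without a call (0.75 ± 0.35), a difference of 3.08 ± 0.36 over both genotypes (adjusted p = 3.14e-05). The day effect of Scgb1a1 was 1.97 ± 0.27 (adjusted p = 0.00015). Tff2 differed by 4.07 ± 0.85, Retnla by 3.51 ± 0.82 and the haemoglobin chaperone Ahsp by 2.96 ± 0.69. The goblet cell gene Clca1 had the largest fitted value (9.09 ± 2.00, adjusted p = 0.0243), which rests on 1 read over the treated KO mice of day 2. Its means in treated control mice were 0.534 ± 0.743 CPM at day 2 and 37.5 ± 39.0 CPM at day 7. The effects of Psapl1 (-4.56 ± 0.78), Syt8 (-3.88 ± 0.52), the autophagy gene Atg9b (-2.77 ± 0.39), Areg (-2.46 ± 0.41) and Clca3a1 (-2.36 ± 0.47) were lower at day 7.

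Of 25 interferon-stimulated genes, 10 had a higher effect at day 7 (18 adjusted over the list alone, median 0.85, adjusted p = 0.0376 with an estimated correlation), led by Rtp4 at 1.18 ± 0.19, with Bst2 at 0.70 ± 0.24 and Rigi at 0.29 ± 0.23 not called. Of 15 injury-associated genes, 6 had a lower effect (12 adjusted over the list alone, median -0.965, adjusted p = 0.0376 with an estimated correlation), with Krt7 at -0.42 ± 0.19 and Clu at -0.96 ± 0.25 not called. Ciliated genes counted 3 lower of 20 (8 adjusted over the list alone, median -0.542, adjusted p = 0.0827 with an estimated correlation), led by Cimap3 at -1.29 ± 0.26. Camera with the preset correlation called 17 lists, of which those first 2 held with an estimated correlation. The gene count was 132 without untreated KO replicate 2 of day 2, 137 or 135 without treated control replicate 1 or 2 of day 2, 334 or 107 without treated KO replicate 2 or 3 of day 2, and 125 without treated KO replicate 1 of day 7. DESeq2 called 364 genes. Days and letters coincide in these libraries, so a change between days cannot be told from a difference between letters.

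Untreated lungs themselves differed between the day labels 7 and 2, with 2835 genes called, 1249 higher and 1586 lower at day 7, of which 544 changed at least 2-fold. The largest increases were the aryl hydrocarbon receptor target Cyp1a1 at 6.29 ± 1.23 (from 0.180 ± 0.115 to 15.9 ± 3.13 CPM in control mice and from 0.061 ± 0.056 to 5.38 ± 6.04 CPM in KO mice, n = 3), the airway secretory gene Bpifa1 at 3.01 ± 0.73, Olfm2 at 2.81 ± 0.38, the adult globin Hbb-bt at 2.5 ± 0.34 and the adipocyte protease Cfd at 2.27 ± 0.42. The largest decreases were the stefins Stfa2 at -3.38 ± 0.68, Cstdc5 at -2.97 ± 0.64 and Stfa1 at -2.75 ± 0.52, Trim67 at -3.27 ± 0.46 and angiotensinogen (Agt) at -2.54 ± 0.46. Of 10 red blood cell genes 9 rose (10 adjusted over the list alone, median 1.67, adjusted p = 0.132 with an estimated correlation), with Hbb-bs at 2.18 ± 0.25 and Hba-a1 at 2.09 ± 0.35. Club cell genes counted 9 higher of 18 (11 adjusted over the list alone, median 0.60, adjusted p = 0.346 with an estimated correlation), with Scgb1a1 at 1.03 ± 0.19 and Cbr2 at 0.60 ± 0.17. Of 15 B cell genes 7 fell (8 adjusted over the list alone, median -0.611, adjusted p = 0.572 with an estimated correlation), with Cd22 at -0.84 ± 0.17 and Ighm at -0.73 ± 0.16. All 6 adipose genes were above 0, with 4 called (5 adjusted over the list alone, median 1.66, adjusted p = 0.346 with an estimated correlation), among them Cfd and Plin1 (1.27 ± 0.33). Camera with the preset correlation called 12 lists, of which 0 held with an estimated correlation. Fry, which does not compare a list with other genes, called 10 lists. Without replicate 3 of the untreated KO mice of day 7, 1720 genes were called, and with a replicate block 935.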

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

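The tests of these differences were fixed before the data were examined. The naphthalene effect differed between day 7 and day 2 for 209 genes and, by camera with the preset correlation, for 17 lists. Scgb1a1 and Scgb3a2 had a higher effect at day 7 (differences of 1.97 ± 0.27 and 3.08 ± 0.36), and Areg and Psapl1 a lower one (-2.46 ± 0.41 and -4.56 ± 0.78). With an estimated correlation 2 of the 17 lists were called, the interferon-stimulated and the injury-associated genes (adjusted p = 0.0376 for each). Days and library letters coincide, so a difference between days cannot be told apart from one between letters.

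The naphthalene effect differed between genotypes for 13 lists at day 2, 1 list at day 5 and 6 lists at day 7 by camera with the preset correlation. None of these was called with an estimated correlation, where the lowest adjusted p over all lists was 0.443, 0.302 and 0.607. By edgeR 0 single genes differed at any day, with 371, 1869 and 882 genes at an unadjusted p under 0.05, and 0 by DESeq2. At day 5 the 1 list was the interferon-stimulated genes (median 0.546, adjusted p = 0.799 with an estimated correlation). Without replicate 1 of the untreated control mice of day 5, camera with the preset correlation called 6 lists at that day and 0 with an estimated correlation (lowest adjusted p = 0.0851).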

How the results depend on the processing

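The self-test without a filter was chosen after the counts without a filter were seen; the other settings here were fixed before the data were examined. Of 505 settings of 75 named-gene results, 437 kept direction and call, 68 kept direction and lost the call, and 0 reversed. Of the 75 results, 32 lost the call in at least 1 setting. The genes had been picked as called in the same counts, so few reversals were possible from the start. Of 111 settings of the counts other than leaving out libraries, 72 stayed within 1.5 times and 39 did not. A count of 0 in both fits was taken as unchanged. All 18 comparisons had a count outside that range in at least 1 setting. With RLE factors no count moved by more than 1.5 times.

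Leaving out each library in turn, a lone library left in a group being assumed to vary as the others do, gave 468 to 784 genes for naphthalene in control mice at day 2, 23 to 3544 at day 5 and 3 to 5 at day 7. In KO mice the ranges were 216 to 1099, 68 to 901 and 4 to 15. The genotype effect ranged from 0 to 197 in untreated mice of day 5, from 0 to 3 in treated mice of day 5 and from 0 to 0 in the other genotype comparisons and the genotype differences. The day 7 minus day 2 difference ranged from 107 to 334 for naphthalene and from 1720 to 3309 in untreated mice.

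DESeq2 called 1329 genes in control mice at day 5 and 15 at day 7, 449 and 31 in KO mice of those days, 25 and 1 for genotype in untreated and treated mice of day 5, and 364 for naphthalene at day 7 minus day 2. The mean of Y-linked genes as a covariate gave 1061 for control mice at day 5. A fit of only the compared groups gave 26 for control mice at day 5 and 3 at day 7, 261 and 24 for KO mice at days 2 and 5, and 2 and 86 for genotype in untreated mice of day 5 and treated mice of day 2. The replicate block gave 167, 9 and 0 for control mice at days 2, 5 and 7, 69 and 46 for KO mice at days 5 and 7, 2, 123 and 1437 for genotype in untreated mice of days 5 and 7 and treated mice of day 7, and 935 for untreated mice at day 7 minus day 2. For all of these the cause was not tested. The letter term gave 0 genes by edgeR wherever it could be fitted, with 1309, 2464 and 520 genes at an unadjusted p under 0.05 for genotype in untreated mice of days 2 and 5 and treated mice of day 5, 443 and 2114 for the genotype differences of days 2 and 5 and 4692 for the averaged effect.

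Without a filter on low counts edgeR called 2118 and 45 genes in control mice at days 5 and 7, 1056, 635 and 161 in KO mice at days 2, 5 and 7, and 603 for naphthalene at day 7 minus day 2. For genotype it called 21, 245 and 33 in untreated and 70, 20 and 231 in treated mice of days 2, 5 and 7, 12, 168 and 51 for the genotype differences of those days, and 503 for the averaged effect. On simulated data for the averaged effect, 59 of 173 calls were false without the filter and 2 of 103 with it. This was run for the averaged effect alone, where 9 of the 503 genes had been removed by the filter; for the other counts the cause was not tested. Of all 43 lists in 18 comparisons, 178 were called with the preset correlation, 24 with an estimated correlation and 77 with fry. At 10.7 to 21.06 M counts, 1 read is 0.049 to 0.089 CPM, which leaves transcripts such as Il5 at a few reads per library.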

Other observations

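Of the tests below, that of the group for the microglia genes and that of the letters at day 7 for the ciliated cell genes were chosen after the result was seen. Replicate 1 of the untreated control mice of day 5 held P2ry12 at 159 CPM, Siglech at 39.5, Gpr34 at 79.2, Trem2 at 81.2, Sall1 at 22, P2ry13 at 38.3 and Cx3cr1 at 108 CPM, against at most 3.92, 0.951, 2.94, 5.99, 1.90, 5.15 and 17.8 CPM in the other 34 libraries. RNA of microglia in that library is a candidate explanation, as it was the highest of 35 for 8 of 14 further microglia genes, such as Ctss at 416 and Csf1r at 224 CPM. Whole brain is argued against by a median log2 ratio of -0.025 for brain genes, more interstitial macrophages by one of 0.12 (2 of 9 genes highest there), and a property of the group by 0 genes with both other libraries of the group above the rest. Tmem119 and Olfml3, also microglia genes, were not higher there.

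Untreated mice differed between days 7 and 2 in 2835 genes. The untreated control mice of day 5 lay at a median position of 0.357 between day 2 (0) and day 7 (1) (0.42, 0.209 and 0.432 in its 3 libraries). This rests on 3 mice and on 38 of the 41 genes called in KO mice alone. The 38 were kept because the control means of days 2 and 7 also lay apart in the same direction. A group unrelated to age could fall between means chosen to lie apart, so the position does not decide on age or time. With 0 letters on both days, a difference between library series cannot be told apart from age or time.

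Ciliated cell genes were higher after naphthalene, with no overlap of the list means of treated and untreated libraries in 6 of 6 combinations of day and genotype. Fewer counts in club cell genes would lift every other gene by 0.01 on the log2 scale, far below the list median of 1.14 in control mice at day 2. At day 7, where all libraries share a letter, at least 19 of the 20 genes were higher in each genotype, which argues against the letters for that day. At days 2 and 5 the letters stay open, and bulk counts do not separate more ciliated cells or loss of other cells from more transcript per cell.

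Other splits of the same libraries were counted. With 10 splits no share under 0.05 can be had. For naphthalene, 1 of 10 splits gave as many genes as the real one in control mice at day 2 (774, highest other 0), day 5 (492, 0) and day 7 (8, 0) and in KO mice at day 2 (565, 394) and day 5 (272, 2). For genotype, 10 of 10 did in untreated mice of day 2 (0, highest other 7), day 5 (0, 707) and day 7 (0, 0) and treated mice of day 2 (0, 2) and day 5 (0, 0). The 707 genes, for control replicates 1 and 2 with KO replicate 2 against the rest, point to a structure of these samples other than genotype. That split keeps both libraries with letter o together, among them the library with microglia genes. With a letter term edgeR called 0 genes for genotype (2464 at an unadjusted p under 0.05). Of 25 splits drawn at random, the real one included, 25 gave as many as the real 0 for the genotype difference at day 2 (highest other 4) and day 5 (1016) and for the averaged effect (0). Which libraries gave the 1016 genes was not examined, so their cause stays open. Where the real count is 0 every split gives as many, so the genotype splits say nothing about chance. For untreated mice at day 7 minus day 2, 1 of 25 did (2835, highest other 22). This is the smallest share that 25 splits can give, so it argues against chance without excluding it. The other splits mix the days, which adds the day difference to the spread within their groups.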
